A study of Rattus norvegicus with 79 samples.

How the data were processed

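The data are 79 arrays of total RNA from the CA1 field of the hippocampus of male Fischer 344 rats aged 3 or 24 months, 1 array per animal. Per the labels, animals were killed 1 day after the last trial, the CA1 cell layer was punched out of brain slices kept in an RNA preservative, and the RNA went through 2 rounds of amplification before labelling with biotin. Amplification from a small punch can favour the 3' end of transcripts, so that probe sets far from that end read lower where RNA is less intact. The deposited values are intensity values, 1 linear signal per probe set and array, made by the authors with MAS5 per the submitters' processing notes. The mean signal of each array, leaving out the highest and lowest 2% of values, lay between 499.92 and 499.95, so the arrays had been scaled to a common level before deposit. The largest value was 848984.8 and 46 values were 0. Scanner images, detection calls and scan dates were not used here. Probe sequences and the genome build behind the probe sets are not given in the sources used here, and no genome coordinates were used.

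Of 8799 probe sets, 59 controls were left out of all tests. Over all probe sets, 7018 had 1 gene symbol and 308 had several; 1426 of the 8740 that were not controls had no symbol in the annotation and are unnamed here. Of the symbols, 6994 were updated through the gene identifier and 24 kept the platform's name. Values were tested as log2(signal + 15), where 15 is the 10th percentile of all values rounded to a whole number. A fold on this log2(value + pseudocount) scale understates the change of genes with low signal. The 40% of probe sets with the lowest mean signal over all arrays were left out, which kept 5244 probe sets, 4284 of them with 1 symbol, and 3233 genes.

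Groups came from the sample titles. The comparisons and their tests were fixed before the data were examined, as were the alternatives except 3. These 3, and most of the tests that weigh explanations, were added after results had been seen and are named where they are given. Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend), two-sided, with the Benjamini-Hochberg adjusted p under 0.05 as the threshold. Comparisons within aged rats used the 44 aged arrays, those within young rats the 19 young arrays, and those with B rats all 60 aged arrays, with 1 mean per group. The age comparison used 63 arrays with treatment as an additive factor, and the interaction was a moderated F test on 3 degrees of freedom.

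Genes were named by a rule. With 1 probe set per gene, that of the highest mean signal among those with 1 symbol, the 10 largest rises and 10 largest falls past the threshold could be named in each comparison. Where fewer than 5 passed, the 5 with the smallest unadjusted p were taken as values only. For each called list, and for 5 fixed lists in the age and the impaired minus unimpaired comparisons, the 4 members with the smallest unadjusted p were also taken. Probe sets without a symbol were limited to 2 that rose and 2 that fell per comparison. Lists of genes for cell types, pathways and complexes, 30 in number, were fixed in advance, and the 29 with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the lists of a comparison.

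No 2 arrays held identical values, and the highest Spearman correlation of any pair was 0.976. Quality was described by 4 values per array: the median Spearman correlation with the other arrays, the disagreement between probe sets of the same gene, the log2 ratio of 3' to 5' control probe sets, and the mean log2 signal of 9 spike-in probe sets. The alternatives were pseudocounts of 1 and 60, no filter and a 60% filter, quantile normalization, median centring, eBayes without trend but robust, array quality weights, the 3' to 5' ratio as a covariate, animal numbers in 4 ranges as a block, 1 fit over all 79 arrays, other probe sets of the same gene, and leaving out each array in turn. The labels do not call the number ranges batches. Added after the data were seen were fits without the 14 arrays of correlation under 0.85, without the 18 arrays of disagreement over 0.75, and with the spike-in signal as a covariate. The fits were tested on simulated data with 200 of 5244 probe sets changed by a log2 size of 0.5 or 1. In the age comparison 29% and 82% of the 100 changed probe sets of each size were recovered, with 3 false calls among 5044. The simulated errors were independent between probe sets and between arrays, with no array that deviated as a whole. The false calls and the shares recovered therefore do not give the error rates of these data.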

Results

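Messenger RNA was measured in the CA1 field of the hippocampus of male Fischer 344 rats, 1 array per animal, after training in a water maze, a pool in which a rat learns to find an escape platform. Young rats were 3 months old and aged rats 24 months old. Cage controls stayed in their cages, yoked controls swam with no platform, visible platform rats could see the platform, and hidden platform rats had to learn where it was. The 19 young arrays came from 3 cage control, 6 yoked, 4 visible platform and 6 hidden platform rats. The 44 aged arrays of the stated design came from 5 cage control, 8 yoked, 8 visible platform, 13 hidden platform unimpaired and 10 hidden platform impaired rats, where impaired refers to learning. A further 16 aged hidden platform arrays carry the letter B, which the labels do not explain.

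Each array held 8799 probe sets, of which 5244 were tested, and the median signal of an array lay between 98.9 and 347.1. For each array, the median Spearman correlation with the other arrays, across probe sets, lay between 0.223 and 0.940, with a median of 0.920 over the 79 arrays. It was under 0.85 on 14 arrays, among them 4 of 8 aged visible platform arrays, 2 of 3 young cage control arrays, 2 of 4 young visible platform arrays and 2 of 10 impaired arrays. None of the 16 B arrays was under 0.85. The number of arrays per group limits the precision of each value. A value after ± is the standard error of a log2 difference unless SD is written, and every adjusted p for a gene is from limma with Benjamini-Hochberg adjustment.

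**Figure D1:**
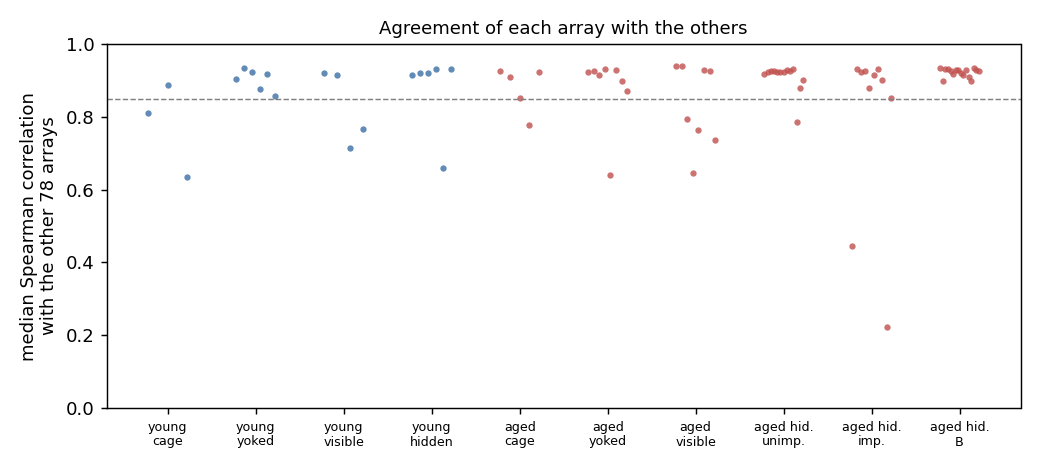
Each point is 1 array, placed by its group on the horizontal axis and by its median Spearman correlation with the other arrays on the vertical axis, with young arrays in blue, aged arrays in red and a dashed line at 0.85. The lowest points are aged impaired arrays 83 and 8, at 0.223 and 0.445.

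The series title sets aged against young rats, and this comparison, adjusted for treatment, held 44 aged and 19 young arrays. C3, the central complement component, rose by 1.25 ± 0.23 on the log2 scale (adjusted p = 0.00047, higher than the young mean of the same treatment in 38 of 44 aged rats). C1qb, a chain of the complement protein C1q, rose by 1.25 ± 0.23 (adjusted p = 0.000632, 40 of 44). Gria1, the AMPA glutamate receptor subunit GluA1, rose by 1.94 ± 0.44 (adjusted p = 0.00441, 37 of 44), and its other probe sets rose by 0.83 ± 0.20 and 1.63 ± 0.45. Lpl, lipoprotein lipase, fell by 1.03 ± 0.19 (adjusted p = 0.000632, 36 of 44). Tac1, the precursor of substance P, fell by 0.85 ± 0.17, and Egr2, an immediate early transcription factor, fell by 0.87 ± 0.21. Other large rises were those of Zswim8 (1.42), the glutathione peroxidase Gpx4 (1.37), the tyrosine kinase Matk (1.32), the cyclic nucleotide phosphodiesterase Pde2a (1.23), the autophagy gene Atg13 (1.22), Rnf112 (1.19) and Atp9a (1.17). Several of these were largest in cage controls. The age difference was 5.42 there and 0.89 in hidden platform rats for Gria1, and 4.66 and 0.23 for Gpx4. It was 3.51 and 0.32 for Pde2a, and 3.78 and 0.76 for Zswim8. C3, C1qb and Lpl also differed least in hidden platform rats. None of these 3 genes, nor Gria1, Gpx4, Pde2a or Zswim8, was among the 7 that passed the interaction test given below. A dependence of their age difference on treatment was therefore not shown. That test does not exclude it either, since it recovered 0% of 100 simulated changes of log2 size 1. The age difference of C3 was 1.68 in cage controls, 1.62 in yoked, 1.87 in visible platform and 0.44 in hidden platform rats. That of C1qb was 2.19 in cage controls and 0.47 in hidden platform rats, and that of Lpl -1.67 and -0.24. Cage controls hold 3 young arrays, 70, 74 and 76, with log2 3' to 5' ratios of 0.05, 2.65 and 0.51. Those of arrays 70 and 76 were low, while that of array 74 lay near that of young hidden array 38, at 2.69. Other large falls were those of the glycine receptor subunit Glra2 (-1.02), the cap-binding subunit Ncbp2 (-0.92), Cyp1b1 (-0.88), Oxr1 (-0.88), Aftph (-0.86), Fkbp3 (-0.84) and the calmodulin-binding gene Pcp4 (-0.81). In all, 269 of 5244 probe sets passed the threshold, 168 that rose and 101 that fell, and 1093 had an unadjusted p under 0.05 against 262.2 expected by chance. Over 161 other probe sets of the called genes, 78.3% differed in the direction of the call, with a median of 0.22 in that direction against 0.79 for the called ones.

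Microglia and complement genes as a list lay higher in aged rats (median log2 difference 0.16 over 20 measured members, camera adjusted p = 0.00487), a call not kept with an estimated correlation between members (adjusted p = 0.0956 with an estimated correlation; fry 0.0018). Of these, 3 rose and 0 fell, and 3 rose adjusted over the list alone: C3, C1qb and Ctsd, the lysosomal protease cathepsin D, by 1.11 ± 0.27. The age difference of Ctsd was 3.35 in cage controls, 1.22 in yoked, 0.76 in visible platform and 0.32 in hidden platform rats. Astrocyte markers had a median of 0.23 over 22 members (camera adjusted p = 0.00487, and 0.281 with an estimated correlation, which ends the call). Of them 2 rose and 0 fell, and 2 rose adjusted over the list alone. These were Aqp4, the astrocyte water channel, by 0.96 ± 0.23, and Slc4a4, a bicarbonate transporter, by 0.92 ± 0.21. Immediate early genes had a median of -0.20 over 25 members, with 1 past the threshold, Egr2, which was also the 1 member past it adjusted over the list alone (camera adjusted p = 0.0753, and 0.281 with an estimated correlation). Of 19 MHC class I and interferon genes, 1 rose, RT1-CE12 by 0.45 ± 0.13, also 1 adjusted over the list alone (camera adjusted p = 0.561, and 0.975 with an estimated correlation). Of 17 oligodendrocyte and myelin genes, 0 passed with limma over all probe sets and 3 rose adjusted over the list alone; Mbp, myelin basic protein, differed by 1.44 ± 0.46 (adjusted p = 0.0502). The list's camera adjusted p was 0.59, and 0.998 with an estimated correlation. Without the 14 arrays of low correlation, an alternative chosen after the data were seen, 727 probe sets passed, 243 of them among the 269; without the 18 arrays on which probe sets of the same gene disagreed most, 287 passed, 120 of them among the 269. Leaving out 1 array gave counts of 171 without young cage array 70, 178 without young cage array 74, 172 without young visible array 65, 419 without aged visible array 68, 426 without young yoked array 59, 431 without aged yoked array 63 and 434 without young hidden array 37. Array quality weights gave 1134, 1 fit over all 79 arrays 450 and the spike-in covariate 498.

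**Figure D2:**
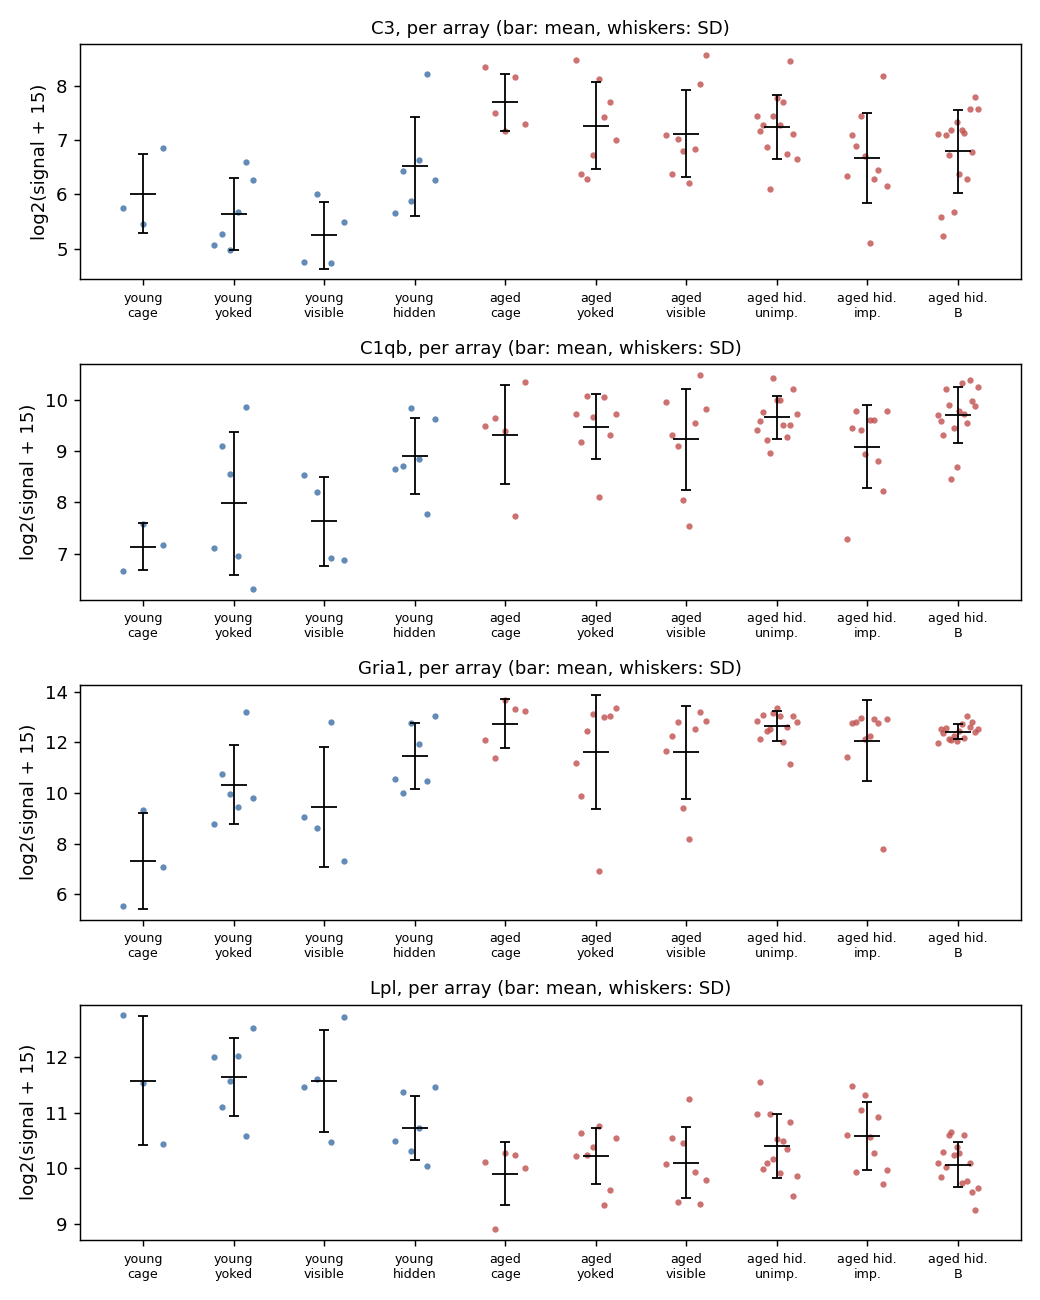
Each point is the log2(signal + 15) of C3, C1qb, Gria1 or Lpl on 1 array, by group, with young rats in blue and aged rats in red; the horizontal bar is the group mean and the whiskers its SD. Mean C3 was 6.01 in young and 7.69 in aged cage controls, and mean Lpl was 11.58 and 9.91. The groups lay closer in hidden platform rats: mean C3 was 6.51 in young, 7.23 in unimpaired and 6.66 in impaired rats. Mean Lpl was 10.74, 10.41 and 10.58 in the same groups.

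Whether the age difference depended on treatment was tested with an interaction on 3 degrees of freedom over the same 63 arrays. Map3k12, a neuronal stress kinase, Ptgds, prostaglandin D2 synthase, and Ece1, endothelin converting enzyme, passed with an adjusted p of 0.00711 each. Ptprs, a receptor tyrosine phosphatase, passed at 0.0332, Ddrgk1 at 0.0388, the ribosomal protein gene Rpl18 at 0.0400 and Hbb-b1, a beta globin chain, at 0.0419; beta globin genes are near-identical copies, and their probe sets can share signal. In cage controls the aged minus young difference of these 7 genes ranged from 2.09 for Ece1 to 5.04 for Ptprs. It ranged from 0.07 to 0.69 in yoked rats, from -0.37 to 0.55 in visible platform rats and from -0.48 to 0.40 in hidden platform rats. The interaction called 16 probe sets, and 751 had an unadjusted p under 0.05. The log2 ratio of 3' to 5' control probe sets varies with RNA and amplification. It was 1.07 ± 1.39 (SD, n = 3) in young cage controls and 3.70 ± 0.93 (SD, n = 5) in aged ones. Loss of signal far from the 3' end would raise this ratio, so the low value in young cage controls is not a sign of it. It does not exclude such a loss either. All 3 young cage arrays were among those on which probe sets of the same gene disagreed most. The lowest ratios, -0.56 on aged visible array 68, -0.31 on impaired array 83 and -0.04 on aged yoked array 63, lay on arrays of correlation under 0.85. What lowers the ratio was not tested. With that ratio as a covariate, 0 probe sets passed in limma, and likewise with animal number range as a block, although no range held both young cage control and young hidden platform rats. The lowest count, 1, was without young cage array 70 and the highest, 125, without young visible array 65; the arrays that moved it by over 1.5 times are given with the dependence on processing. Over the 168 probe sets that rose with age, the median difference was 1.93 in cage controls, 0.92 in yoked, 0.93 in visible platform and 0.34 in hidden platform rats, values whose differences were not tested.

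Impaired and unimpaired aged rats had the same hidden platform training and differed in learning (10 and 13 rats). No probe set passed the threshold: limma called 0 of 5244, with 677 at an unadjusted p under 0.05 and a smallest adjusted p of 0.312. The genes with the smallest unadjusted p were Plagl1, a zinc finger transcription factor (1.40 ± 0.38), Rgn (1.20 ± 0.33), the ribosomal protein gene Rpl6 (-1.22 ± 0.34), Ldhb, a lactate dehydrogenase subunit (-0.83 ± 0.24), and the DNA polymerase alpha subunit Pola2 (1.13 ± 0.32). For Rpl6 and Ldhb, all 10 impaired rats lay below the unimpaired mean. The count was 0 under every alternative tried and without any 1 of the 23 arrays. Simulated changes of log2 size 1 were recovered for 31% of 100 changed probe sets in this comparison.

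Camera called 9 gene lists between impaired and unimpaired rats, and for all 9 the adjusted p was 0.595 with an estimated correlation, so that none kept its call; fry called 0 lists and 0 members passed with limma over all probe sets. Ribosomal proteins had a median log2 difference of -0.47 (36 of 41 lower, camera adjusted p = 7.9e-07), genes of the proteasome list -0.43 (20 of 20 lower, 8.4e-05) and oxidative phosphorylation genes -0.35 (38 of 41 lower, 4.9e-05). Examples were Rpl3 at -0.94 ± 0.33, the proteasome subunits Psmd2 at -1.06 ± 0.37 and Psma4 at -0.79 ± 0.29, and the ATP synthase subunit Atp5pf at -0.85 ± 0.32. CA1 and pyramidal neuron markers had a median of -0.44 (11 of 12 lower, 0.0429), cytoskeleton genes -0.40 (20 of 27 lower, 0.0149) and astrocyte markers -0.40 (17 of 22 lower, 0.0270). Examples were Hpca, the calcium sensor hippocalcin (-0.85 ± 0.40), Nefl, neurofilament light chain (-0.70 ± 0.25), and Sparcl1 (-0.89 ± 0.38). Monoamine and cholinergic receptors lay the other way, with a median of 0.52 (23 of 28 higher, 4.0e-05); the adrenergic receptor Adra2c differed by 0.80 ± 0.25 and the serotonin receptor Htr7 by 0.98 ± 0.34. Endothelial and mural markers had a median of 0.43 (18 of 21 higher, 0.00777) and growth factors and their receptors 0.29 (31 of 38 higher, 0.0133), with Kcnj8, a pericyte potassium channel, at 0.85 ± 0.37 and the insulin-like growth factor receptor Igf1r at 0.78 ± 0.26 (-0.00908 by another probe set). Adjusted over the list alone, 1 ribosomal protein gene, Rpl6, fell and 0 members of the other 8 lists passed. Across probe sets the log2 difference fell with mean signal (Spearman -0.672, or -0.317 without the arrays of low correlation; probe sets are not independent replicates). Without those arrays the ribosomal, proteasome, monoamine receptor and endothelial lists kept their camera calls and the other 5 lost theirs, and the ribosomal median was -0.18 and the receptor median 0.39. Of the lists examined whatever their test, immediate early genes had a median of 0.09 (camera adjusted p = 0.672, direction down, so that median and test differ in sign), microglia and complement -0.11 (0.733), MHC class I and interferon 0.11 (0.585) and oligodendrocyte and myelin -0.17 (0.284). None of their members passed, over all probe sets or adjusted over the list alone, and the lowest adjusted p of the 4 was 0.680 with an estimated correlation. Members with a small unadjusted p went both ways: Nr4a1, an activity-induced nuclear receptor (-0.71 ± 0.26, and -0.00629 by another probe set), and Ptgs2, cyclooxygenase 2 (0.81 ± 0.31, and -0.0182), among immediate early genes, and B2m, the MHC class I light chain (-0.89 ± 0.28), and Rsad2 (0.81 ± 0.38) among MHC and interferon genes.

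**Figure D3:**
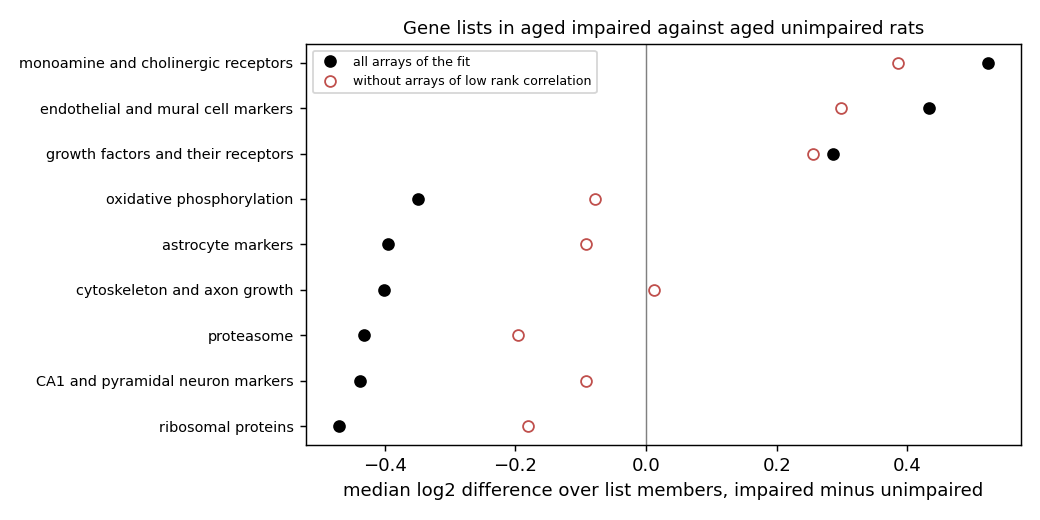
Each pair of points is 1 gene list, with the median log2 difference of its members, impaired minus unimpaired, on the horizontal axis; filled points hold all arrays of the fit and open points leave out the arrays of low correlation. The ribosomal median is -0.47 with all arrays and -0.18 without those of low correlation.

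Hidden platform rats were set against each control group within the aged rats, with hidden the mean of impaired and unimpaired (23 rats). Against 8 visible platform rats, which also swam to a platform, Gstk1, a mitochondrial glutathione transferase, fell by 1.87 ± 0.37 (adjusted p = 0.0301, lower in 23 of 23), while its other probe set differed by 0.10. It was the 1 probe set past the threshold, with 598 at an unadjusted p under 0.05. Next were the caspase Casp2 (1.30 ± 0.31), the co-chaperone St13 (0.93 ± 0.23), Grpel1 (0.96 ± 0.24) and Ptms (-1.11 ± 0.28), each with an adjusted p of 0.108; other probe sets of Casp2 and St13 differed by -0.12 and -0.0601. None of the 29 lists was called. The call of 1 was lost, with a count of 0, under quantile normalization, median centring and the spike-in covariate, without the arrays of low correlation or of high disagreement, and without any one of aged visible arrays 31, 96 and 97 or impaired array 51. Gstk1 still lay lower in hidden platform rats under each of these alternatives, where the omissions of single arrays are not counted. The count was 9 without aged visible array 69, 4 without impaired array 8, 3 without impaired array 47, and 2 without any one of aged visible arrays 32 and 67, unimpaired array 81 and impaired array 87.

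Against 8 aged yoked rats, which swam with no platform, limma called 0 probe sets, with 155 at an unadjusted p under 0.05. Oligodendrocyte and myelin genes had a median of -0.23 in hidden platform rats (15 of 17 lower, camera adjusted p = 0.0136, and 0.684 with an estimated correlation). Of the 17, 0 passed over all probe sets and 1 fell adjusted over the list alone, Mal, a myelin proteolipid (-0.75 ± 0.23); Mag, myelin-associated glycoprotein, differed by -0.54 ± 0.21 and the connexin gene Gjb1 by -0.57 ± 0.25. Other genes with a small unadjusted p were the filamin Flnc (-0.85 ± 0.24) and Ppp1r9b, a dendritic spine scaffold (-0.78 ± 0.23). Array quality weights gave 8 probe sets.

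Against 5 aged cage controls, which had no maze experience, limma called 0 probe sets, with 449 at an unadjusted p under 0.05. Ribosomal protein genes lay lower in hidden platform rats, with a median of -0.75 (39 of 41 lower, camera adjusted p = 4.4e-21), a call not kept at an adjusted p of 0.0918 with an estimated correlation. Over all probe sets 0 of them passed, and 10 fell adjusted over the list alone, among them Rpl27a (-1.53 ± 0.40), Rpl26 (-1.45 ± 0.41) and Rpl24 (-1.23 ± 0.35). Across probe sets the log2 difference fell with mean signal (Spearman -0.274, or -0.0659 without the arrays of low correlation). Oxidative phosphorylation (median -0.40, adjusted p = 3.2e-08), proteasome (-0.49, 1.4e-05), astrocyte (-0.43, 0.000636) and cytoskeleton genes (-0.20, 0.0490) also lay lower, and markers of neighbouring hippocampal fields higher (0.25, 0.0253). In these 5 lists 0 members passed over all probe sets; adjusted over the list alone 1 proteasome gene fell, Psmd4 (-0.995 ± 0.294), and 0 members of the other 4 passed. Their adjusted p was 0.540, 0.540, 0.321, 0.819 and 0.179 with an estimated correlation, and fry called the neighbouring fields list upward (adjusted p = 0.0414). The astrocyte genes Sparc (-1.31 ± 0.43) and Apoe (-1.08 ± 0.48) and Nptx1, a neuronal pentraxin on the list of neighbouring fields (0.67 ± 0.28, and -0.21 by another probe set) were among the members with the smallest unadjusted p. Mean log2 spike-in signal, which can be higher where less labelled sample reached the array, was 13.2 ± 2.45 (SD, n = 5) in cage controls, 11.5 ± 0.959 (SD, n = 13) in unimpaired and 11.9 ± 1.92 (SD, n = 10) in impaired rats. Without the arrays of low correlation 70 probe sets passed, without those of high disagreement 40, with array quality weights 118, and without impaired array 83 alone 1.

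In young rats, hidden platform training was set against the same 3 controls. Against 3 cage controls, 6 hidden platform rats had higher Ptprs (4.76 ± 0.71, adjusted p = 0.00329), Mbp (4.70 ± 1.01, 0.0165), Gria1 (4.16 ± 1.01, 0.0262) and Gpx4 (4.0 ± 0.89, 0.0201), each higher in 6 of 6. Further rises were those of Itpka, an inositol trisphosphate kinase of dendritic spines (3.75), the actin regulator Coro1a (3.65), the spectrin Sptan1 (3.63), Ndrg2 (3.5), the beta globin gene Hbb (3.47) and the synaptic vesicle gene Vamp2 (3.41). Falls were those of P2ry12, the microglial ADP receptor (-2.64 ± 0.63), the glucose transporter Slc2a1 (-2.33 ± 0.58), Ptprm (-2.27), Rpl39 (-2.13), Rev1 (-2.10), Taf1 (-2.08), Bend3 (-1.97), Ssbp2 (-1.94), Ywhaz (-1.91) and Bdh1 (-1.91). Other probe sets of Vamp2, Slc2a1 and Ywhaz differed in the opposite direction, at -0.77, 1.87, and 0.85 and 2.65. Other probe sets of Ptprs differed by 1.34 and 1.59 and those of Gria1 by 0.63 and 2.07, all short of the threshold, and the median over other probe sets of called genes, in the direction of the call, was 0.37 against 2.16 for the called ones. In all, 277 probe sets passed, 228 that rose and 49 that fell, with 1250 at an unadjusted p under 0.05. None of the 29 lists was called by camera. Fry called antioxidant enzymes upward (adjusted p = 0.0265); of 26 members 5 rose and 1 fell, and 8 rose and 1 fell adjusted over the list alone, while the camera adjusted p was 0.121, and 0.370 with an estimated correlation. The 3' to 5' log2 ratio was 1.07 ± 1.39 (SD, n = 3) in cage controls against 3.26 ± 0.41 (SD, n = 6) in hidden platform rats, and the median of all log2 differences was -0.13. The count was 0 with that ratio as a covariate, 0 with animal number range as a block (no range held rats of both groups, so this 0 says little), 7 without the arrays of low correlation (1 cage control left, assumed to vary like the other groups), 13 with the spike-in covariate, 145 with median centring, 748 with 1 fit over all 79 arrays and 1484 with array weights. It was 4 without cage array 70, 34 without cage array 76, 533 without cage array 74, and 56, 89, 106 and 116 without hidden arrays 37, 40, 3 and 38.

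Against 4 young visible platform rats limma called 0 probe sets, with 274 at an unadjusted p under 0.05. The mitochondrial creatine kinase Ckmt1 differed by -1.17 ± 0.36, the small heat shock gene Hspb6 by 0.98 ± 0.31 and the lipid kinase Pi4kb by -0.97 ± 0.31 (0.12 by another probe set), each with an adjusted p of 0.836. Against 6 young yoked rats limma called 0 probe sets, with 93 at an unadjusted p under 0.05. Gstt2, a glutathione transferase, differed by -1.62 ± 0.47 (0.0781 by another probe set), Rapgef3, a cAMP-activated exchange factor, by 1.29 ± 0.38, and Nr3c1, the glucocorticoid receptor, by 0.76 ± 0.27, each with an adjusted p of 0.999. None of the 29 lists was called in either comparison. Simulated changes of log2 size 1 were recovered for 0% of 100 probe sets against visible platform rats and 2% against yoked rats. Array quality weights gave 22 probe sets against visible platform rats, and 1 fit over all 79 arrays gave 1.

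Unimpaired and impaired aged rats were each set against young hidden platform rats. For 13 unimpaired against 6 young rats limma called 0 probe sets, with 143 at an unadjusted p under 0.05; the nicotinic receptor Chrna1 (-1.14 ± 0.37) and the potassium channel Kcnd3 (-1.32 ± 0.45) had the smallest unadjusted p. Camera called 8 lists, none of which kept its call with an estimated correlation (lowest adjusted p = 0.538 with an estimated correlation). Across probe sets the log2 difference was larger at higher mean signal (Spearman 0.382, or 0.175 without the arrays of low correlation). Microglia and complement (median 0.18), astrocyte (0.34), CA1 and pyramidal neuron (0.31) and cytoskeleton genes (0.20) lay higher in unimpaired rats. Interneuron markers (-0.27), monoamine and cholinergic receptors (-0.30), endothelial and mural markers (-0.39) and choroid plexus and meningeal markers (-0.27) lay lower. In the 8 lists 0 members passed, over all probe sets or adjusted over the list alone. C1qb differed by 0.75 ± 0.39, Slc4a4 by 0.82 ± 0.36, and Npy, neuropeptide Y, by -0.82 ± 0.36. Dcn stands in both the CA1 and the choroid plexus list and differed by -1.23 ± 0.53. For 10 impaired against 6 young rats limma called 0 probe sets, with 232 at an unadjusted p under 0.05; Sst, somatostatin, differed by -1.32 ± 0.36 (adjusted p = 0.859). Camera called 6 lists, and with an estimated correlation none kept its call. Across probe sets the log2 difference fell with mean signal (Spearman -0.440, or -0.127 without the arrays of low correlation, which include impaired arrays 8 and 83). Interneuron markers had a median of -0.37 (12 of 14 lower, camera adjusted p = 0.000738, fry 0.0352, and 0.107 with an estimated correlation); 0 passed over all probe sets and Sst alone, 1 gene, fell adjusted over the list alone. Ribosomal proteins (-0.45), oxidative phosphorylation (-0.36), oligodendrocyte and myelin (-0.32) and proteasome genes (-0.31) lay lower and monoamine and cholinergic receptors higher (0.20). In these 5 lists 0 members passed, over all probe sets or adjusted over the list alone, and the adjusted p ranged from 0.511 to 0.762 with an estimated correlation. Array quality weights gave 100 probe sets for unimpaired and 85 for impaired rats.

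The 16 aged hidden platform rats marked B were set against the other aged hidden platform rats. Against 13 unimpaired rats 3 probe sets passed, with 376 at an unadjusted p under 0.05. They lie outside the rule for named genes and were chosen after their values were seen: 1 of the 3 probe sets of Sparc, a matrix glycoprotein, rose by 1.33 ± 0.21 while the others differed by -0.29 and 0.22, 1 of 2 probe sets of Ina, alpha-internexin, rose by 1.23 ± 0.26 while the other differed by 0.15, and 1 without a symbol fell by 1.13 ± 0.24. By the rule, Camk2n1, an inhibitor of CaM kinase II, differed by 1.48 ± 0.36 and the potassium channel Kcna1 by 0.98 ± 0.26. Camera called oxidative phosphorylation (median -0.15, adjusted p = 0.0198) and heat shock genes (-0.20, 0.0449), with 0 members past the threshold over all probe sets and 0 adjusted over the list alone; both had an adjusted p of 0.966 with an estimated correlation. Without the arrays of low correlation 87 probe sets passed and without those of high disagreement 140; the count was 436 with array weights, 13 with the 3' to 5' ratio and 1 with quantile normalization, and with the spike-in covariate it was 3 again but held only 1 of the same 3. It was 5 without B array 10 and 1 without any one of unimpaired arrays 7, 15 and 89 or B arrays 9, 11, 12, 13, 41, 46, 86 and 88.

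Impaired rats differed from B rats at 629 probe sets, 325 that rose and 304 that fell, with 1685 at an unadjusted p under 0.05 (10 and 16 rats). The splicing factor Sf3b1 rose by 1.79 ± 0.41, the exchange factor Arhgef4 by 1.63 ± 0.34, the complement regulator Cd55 by 1.60 ± 0.34 and Gstt2 by 1.58 ± 0.31 (adjusted p = 0.00139), each higher in 10 of 10. Dlgap4, a postsynaptic scaffold, fell by 1.56 ± 0.29 (adjusted p = 0.00073), Atn1 (-1.64 ± 0.33) and the autophagy gene Gabarap (-1.49 ± 0.31) fell as well, each lower in 10 of 10. Of 41 ribosomal protein genes 9 fell and 1 rose, and 16 fell and 2 rose adjusted over the list alone (median -0.53, camera adjusted p = 0.000239); Rpl6 fell by 1.28 ± 0.30 and Rps24 rose by 1.28 ± 0.33. Of 20 proteasome genes 4 fell, and 4 fell adjusted over the list alone (-0.35, 0.00306), with Uchl1, a neuronal ubiquitin hydrolase, at -1.26 ± 0.37. Of 12 CA1 and pyramidal markers 1 fell, and 1 adjusted over the list alone, Neurod2, a neuronal transcription factor, by 1.11 ± 0.27 (-0.49, 0.0356). Of 28 monoamine and cholinergic receptors 5 rose, and 6 adjusted over the list alone (0.60, 0.00024), with the nicotinic receptor Chrna4 at 1.41 ± 0.37 and the muscarinic receptor Chrm5 at 1.12 ± 0.34. For all 4 lists the adjusted p was 0.732 with an estimated correlation. Mean log2 spike-in signal was 11.9 ± 1.92 (SD, n = 10) in impaired and 10.4 ± 0.717 (SD, n = 16) in B rats, and the log2 difference fell with mean signal across probe sets (Spearman -0.603, or -0.214 without the arrays of low correlation). Over 261 other probe sets of the called genes, 70.5% differed in the direction of the call, with a median of 0.25 against 0.92. Without the arrays of low correlation 490 passed, 307 of them among the 629; with the spike-in covariate 116 passed (34 up, 82 down), with no filter 1864 (1472 up, 392 down) and with the stricter filter 409 (120 up, 289 down), so the near-even balance of directions depends on these choices. The count was 187 without impaired array 83, 201 without impaired array 8, 402 without impaired array 50, and 407, 382 and 415 without B arrays 90, 12 and 13.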

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

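The splits of the samples, the test of direction over other probe sets and the test of training in aged rats were chosen before their results were seen; the tests of the 3' to 5' ratio, of arrays of low correlation, of spike-in signal, of arrays of high disagreement and of fewer neurons were chosen, and the bounds of the spike-in test revised, after results had been seen.

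Single arrays stood apart from their groups in 6 of 49 groups and measures tested. Chance gives about 1 in 20 for independent tests, which measures of the same arrays are not. The groups of 3 young cage control, 13 unimpaired and 16 B arrays were not tested. Impaired arrays 83 and 8, with the lowest correlations at 0.223 and 0.445, were not flagged on that measure, since the test compares the lowest array with the next lowest. Log2 C1qb was 8.10 on aged yoked array 63, with the next lowest at 9.18. On the same array log2 Ptprs was 6.90 against 11.16, and the median correlation with other arrays was 0.642 against 0.872. Log2 Gria1 was 7.78 on impaired array 83 against 11.43, and log2 Lpl 8.91 on aged cage array 36 against 10.01. The median correlation was 0.661 on young hidden array 39, with the next lowest at 0.917. The age difference of 7 genes differed between treatments by the interaction test, with an adjusted p of 0.00711 for Map3k12, Ptgds and Ece1, 0.0332 for Ptprs, 0.0388 for Ddrgk1, 0.0400 for Rpl18 and 0.0419 for Hbb-b1.

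Other splits of the same arrays, the real one included, were counted by whether they called as many probe sets. The share was under 0.05 for age (2 of 100 splits, 269 against a highest other of 395) and young hidden platform minus cage control (3 of 84, 277 against 1144). It was also under 0.05 for the interaction (4 of 100, 16 against 607), B minus unimpaired (1 of 100, 3 against 1) and impaired minus B (1 of 100, 629 against 303). These shares are not adjusted over the comparisons and do not by themselves exclude chance. For aged hidden minus visible platform 4 of 100 splits called at least the real 1 probe set, with a highest other of 209; any split with a call reaches a count of 1, so this adds little to the call itself. Splits that called several times the real count point to a structure of the arrays, and what those splits share was not tested. For the comparisons with a count of 0 in limma, all 100 of 100 splits reach it by construction, so the splits say nothing about chance there. The highest other counts were 1 for impaired minus unimpaired (677 at an unadjusted p under 0.05), 0 for aged hidden minus yoked (155), 1 for aged hidden minus cage control (449), 87 for young hidden minus visible platform (274), 0 for young hidden minus yoked (93), 0 for unimpaired minus young (143) and 869 for impaired minus young (232).

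Young hidden platform and cage control rats differed at 277 probe sets. Of them, 37.2% (103 of 277) differed in the same direction in aged rats, with a median of -0.10 against 2.23 in the young. This share lay below the bound set beforehand for training that acts alike at both ages. The log2 3' to 5' ratio was 1.07 ± 1.39 (SD, n = 3) in young cage controls against 3.26 ± 0.41 (SD, n = 6) in young hidden platform rats. In aged rats it lay slightly the other way, within its spread. It was 3.70 ± 0.93 (SD, n = 5) in cage controls, 3.44 ± 0.52 (SD, n = 13) in unimpaired and 2.88 ± 1.21 (SD, n = 10) in impaired rats. Whether so small a difference could hide a shared effect was not tested, so the share does not decide the question. An effect of training in young rats alone stays open too. Differences in RNA and amplification may account for the calls. Over 70 arrays of the other groups, centred on group means, the score of the 277 probe sets correlated with the 3' to 5' ratio at Pearson r = 0.711. The permutation p was 1e-05, the smallest possible, and Spearman was 0.353 (permutation p = 0.0031). Without the 2 farthest arrays r was 0.636. Low ratios and low correlation were shared by aged visible arrays 67 and 68, aged yoked array 63, young visible array 65 and impaired array 83. Leaving out 2 arrays keeps some of these in, so a few such arrays may carry much of r. With that ratio as a covariate the median size went from 2.23 to 1.18 and its standard error from 0.577 to 0.590, so that 0 calls were left because the size fell, while all 277 kept their direction. Whether the part of the transcript measured matters stays open. Of 162 other probe sets of the called genes, 65.4% moved in the direction of the call (95% interval 57.6 to 72.7), between the bounds set beforehand. The interval takes probe sets as independent and is too narrow, since they belong to 107 genes on the same arrays.

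Impaired and B rats differed at 629 probe sets. Without the arrays of low correlation 48.8% of the calls (307) were kept, and the median size went from 0.913 to 0.596 with a standard error of 0.266 and 0.20. With spike-in signal as a covariate the median size kept was 76% (quartiles 68.8 and 86.5) and 106 of the 629 stayed past the threshold. Neither value decides whether these arrays, or the amount of labelled sample, could be the cause. No biological explanation was tested, because the labels do not say what B means.

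Microglia and complement genes lay higher in aged rats by camera at the preset correlation (adjusted p = 0.00487), a call not kept with an estimated correlation (adjusted p = 0.0956). Without the arrays of high within-gene disagreement the list median was 0.26 (camera adjusted p = 7.3e-05), against 0.16 over all arrays. That fit held no young cage control. Cage controls had the smallest age difference of the list score, 0.126, so the 2 medians cannot be compared directly. The list still lay higher in the other treatments, which argues against these arrays as the whole cause there. For cage controls the fit does not decide it. A smaller share of neurons in the aged punches may raise every other cell type and stays open. The mean over 38 oligodendrocyte and endothelial genes was 0.029 (-0.094 to 0.153), an interval that holds the bound of 0.078. The interval reflects the spread between genes measured on the same arrays, which are not independent. It does not give the uncertainty over animals, so it cannot decide the question. Neuronal genes went both ways: Gria1 (1.94), Cabp1 (0.79), Syp (0.88), Sv2a (0.79), Rab3a (0.77), Vamp2 (0.95) and Napa (0.71) rose, which a smaller share of neurons alone would not bring, while Tac1 (-0.85) and Sst (-0.67) fell, and the median of 12 CA1 and pyramidal markers was 0.31 (camera adjusted p = 0.219). A limit on these rises is that Gria1 and Vamp2 also rose in young hidden platform rats against cage controls. The same young cage arrays enter the age comparison. The age difference of Gria1 was 5.42 in cage controls and 0.89 in hidden platform rats. Age itself, which the design names, stays open too.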

How the results depend on the processing

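Fits without arrays of low correlation, without arrays of high disagreement and with the spike-in covariate were chosen after seeing the data. No paired analysis was possible because each animal number occurs once. The cause of the changes below was not tested. Impaired minus unimpaired kept a count of 0 in limma (677 at an unadjusted p under 0.05) in every alternative. Aged hidden minus visible platform, 1 probe set, gave 3 with the 60% filter, 0 with quantile normalization, 0 with median centring, 513 with array weights, 9 with the 3' to 5' ratio, 8 with all 79 arrays, and 0 without low-correlation arrays, without high-disagreement arrays and with the spike-in covariate. Aged hidden minus yoked gave 8 with weights. Aged hidden minus cage control gave 118 with weights, 70 without low-correlation and 40 without high-disagreement arrays. Young hidden minus visible platform gave 22 with weights and 1 with all 79 arrays. Young hidden minus cage control, 277, gave 145 with median centring, 1484 with weights, 0 with the 3' to 5' ratio, 0 with the number range block, 748 with all 79 arrays, 7 without low-correlation arrays and 13 with the spike-in covariate. Age, 269, gave 1134 with weights, 450 with all 79 arrays, 727 without low-correlation arrays and 498 with the spike-in covariate. It gave 209 with the number range block, 157 of them among the 269. The interaction, 16, gave 43 with the 60% filter, 6 with median centring, 10 with the robust fit, 1850 with weights, 0 with the 3' to 5' ratio, 0 with the number range block, 194 with all 79 arrays, 79 without low-correlation arrays and 81 with the spike-in covariate. No number range held both young cage control and young hidden platform rats, so the block leaves little of that difference to test. Weights gave 100 for unimpaired minus young and 85 for impaired minus young. B minus unimpaired, 3, gave 1 with quantile normalization, 436 with weights, 13 with the 3' to 5' ratio, 87 without low-correlation and 140 without high-disagreement arrays; with the spike-in covariate 3 passed, 1 of them among the same 3. Impaired minus B, 629, gave 1864 with no filter, 409 with the 60% filter, where fewer probe sets were tested, and 116 with the spike-in covariate. Its calls, 325 up and 304 down, became 1472 and 392 with no filter, 120 and 289 with the 60% filter, 34 and 82 with the spike-in covariate, 293 and 422 with the number range block and 283 and 403 with median centring. The estimation of weights did not converge in some fits. Fits without high-disagreement arrays could not be run for young hidden minus cage control and the interaction, because no young cage control was left. Leaving out 1 array gave 0 to 9 for aged hidden minus visible platform, 0 to 1 for aged hidden minus cage control, 4 to 533 for young hidden minus cage control, 171 to 434 for age, 1 to 125 for the interaction, 1 to 5 for B minus unimpaired, 187 to 895 for impaired minus B, and 0 to 0 elsewhere. The interaction gave 41, 9, 7 and 10 without young hidden arrays 2, 3, 37 and 40, 31 and 40 without young yoked arrays 58 and 60, 31 and 125 without young visible arrays 30 and 65, 1, 71 and 10 without young cage arrays 70, 74 and 76, 8, 9, 5 and 8 without aged cage arrays 35, 36, 99 and 100, 78 and 31 without aged yoked arrays 63 and 94, 56 and 71 without aged visible arrays 67 and 68, and 38 and 60 without impaired arrays 8 and 83. Named genes reversed in 28 cases, nearly all through another probe set of the gene. In impaired minus unimpaired these gave -0.0182 for Ptgs2, 0.39, 0.71 and 0.16 for Slc1a3, -0.24 for Mag and -0.00908 for Igf1r. In aged hidden platform rats they gave 0.10 for Gstk1, -0.12 for Casp2 and -0.0601 for St13 against visible platform, 0.37 for Ptms against yoked, and 0.23 for Entpd2, -0.21 for Nptx1 and 0.48 for Ncam1 against cage controls. In young hidden platform rats they gave 0.12 for Pi4kb, 0.0781 for Gstt2, -0.77 for Vamp2, 1.87 for Slc2a1, and 0.85 and 2.65 for Ywhaz, and Itpka was -0.42 with the number range block. With age they gave 0.14 and 0.35 for Homer1 and 0.20 for Car2, in unimpaired minus young -0.16 and -0.0320 for Slc1a3 and 0.0301 for Nos3, and in impaired minus young 0.22 for Cox6c and 0.11 for Psma5. List tests turned direction for immediate early genes in impaired minus unimpaired (median 0.13 without low-correlation and without high-disagreement arrays), MHC class I genes there (0.17 with no filter, 0.0805 without either set of arrays) and, without high-disagreement arrays, for MHC class I (-0.0276) and myelin genes (-0.0479) with age. Of the other gene results 4096 kept direction and side of the threshold, 222 lost and 117 gained a call; of the list results 159 kept both, 145 lost and 4 gained a call.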

Other observations

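The genes of the first 2 paragraphs and the test of the third were chosen after results had been seen.

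Synaptic vesicle genes lay among those that rose with age. Of 25 measured, 5 rose and 0 fell, and 5 rose adjusted over the list alone: Syp, the vesicle protein synaptophysin (0.88 ± 0.21), Sv2a (0.79 ± 0.18), the vesicle GTPase Rab3a (0.77 ± 0.22), Vamp2 (0.95 ± 0.29) and Napa, a fusion cofactor (0.71 ± 0.23). The list's camera adjusted p was 0.0753, and 0.335 with an estimated correlation. The young cage arrays, which include arrays of low correlation, enter this comparison. Vamp2 also rose in young hidden platform rats against those arrays, where another of its probe sets differed in the opposite direction. Age differences within each treatment are not given for these 5 genes. Of 27 cytoskeleton and axon growth genes 2 fell, Gap43 (-0.70 ± 0.16) and Marcks (-0.57 ± 0.17), and adjusted over the list alone 2 fell and 1 rose (camera adjusted p = 0.39, and 0.975 with an estimated correlation). Of 41 oxidative phosphorylation genes 3 fell with age, and 4 adjusted over the list alone, Ndufs4 by 0.70 ± 0.16, Ndufa6 by 0.67 ± 0.20 and Cox6c by 0.67 ± 0.21 (camera adjusted p = 0.447, and 0.998 with an estimated correlation).

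Interneuron peptide genes went both ways over the comparisons, and few passed. With age Tac1 fell by 0.85 ± 0.17 and Sst, somatostatin, fell by 0.67 ± 0.21 (adjusted p = 0.0414), 2 of 14 interneuron markers; adjusted over the list alone 5 fell and 1 rose. Fry called the list downward (adjusted p = 0.0175), while camera gave 0.192, and 0.57 with an estimated correlation. In impaired against B rats Sst fell by 0.90 ± 0.24 (adjusted p = 0.0144) and Npy fell by 0.67 ± 0.21 (0.0332). Sst differed by -0.86 ± 0.27 in aged hidden against visible platform rats (adjusted p = 0.217) and by -0.78 ± 0.27 in impaired against unimpaired rats (0.312). Npy differed by -0.77 ± 0.23 in aged hidden against visible platform rats (adjusted p = 0.190; 0.0155 adjusted over the list alone, as for Sst), and Tac1 by -1.04 ± 0.37 in young hidden platform rats against cage controls (0.0937). Against these stand Npy at 1.44 ± 0.62 in young hidden against visible platform rats (adjusted p = 0.836) and at 0.50 ± 0.20 in B against unimpaired rats (0.462). Tac1 differed by 0.25 and 0.35 in aged hidden platform rats against visible platform rats and cage controls, and by -0.00729 in impaired against unimpaired rats. These comparisons share arrays and are not independent. With age, fry called 5 lists: besides interneuron markers, microglia and complement genes upward, immediate early genes and markers of neighbouring fields downward (adjusted p = 0.0018 each) and glucocorticoid response genes downward (0.0175).

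A hypothesis was that the age difference in microglia and complement genes is smaller after hidden platform training. The age difference of the list score was 0.171 in hidden platform rats, 0.126 in cage controls, 0.469 in yoked and 0.410 in visible platform rats. Hidden platform rats differed from the mean of the other 3 treatments by -0.164 (permutation p = 0.18, 63 arrays), and by -0.158 (p = 0.202, 49 arrays) without the arrays of low correlation. The test does not decide the hypothesis; what would count against it was set after the values were seen.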
